A study of Homo sapiens with 18 samples.

How the data were processed

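Total RNA of MRC5 fibroblasts was sequenced in 18 libraries, 3 for each of 6 groups. The groups were control cells (NF) and TGFB1-treated cells (CAF) in 2D, on a soft collagen scaffold and on a stiff one. Each library's group and replicate letter were taken from its label. The labels were kept as deposited throughout, also where the values raised a doubt about them. RNA was extracted with a Qiagen kit and libraries were made and sequenced by Novogene, per the labels. The library kit, its strandedness and the read length were not given in the sources used here.

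The values were raw counts per gene, deposited by the authors in 3 tables, 1 per substrate, each with 1 column per library and no pooling, per the file headers. They were whole numbers with different totals per library. STAR, DESeq2 and the genome builds GRCh38 and hg38 are named, without versions or roles, per the submitters' processing notes. The counting program, the annotation release and any filter were not given in the sources used here. Each table held the same 58825 Ensembl genes. Of these 27240 had no count in any library. Gene symbols were matched for 58472 from a table of Ensembl identifiers, and 58552 were found in GENCODE release 29, which gave the length and GC content of each gene's longest transcript. Gene positions are those of the RefSeq annotation of GRCh38.p14, as the tables hold no coordinates. Whether counting used strand is not known, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Genes with near-identical relatives, such as the PSG, ADH1 and globin families and the actins, may share reads and are uncertain.

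Totals per library lay between 62190684 and 84073624 counts. No molecular identifiers were stated, and PCR copies were not removed here. Floors therefore cover counting error only, while each SD and SE holds the spread between libraries. The most frequent low count of each library was read from its histogram of counts from 4 to 60, smoothed over 5 values. All pairs of replicates within a group were compared by a chi-square test of their counts over genes, and no pair was identical or within sampling noise (23.2 to 445 per degree of freedom).

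Differential expression was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts of all 18 libraries in 1 model with a term per group. Genes were kept by filterByExpr, which left 20054. Library sizes were scaled by TMM, with factors from 0.883 to 1.086. The common biological coefficient of variation was 0.432, with 12 residual and 6.2 prior degrees of freedom. The contrasts were CAF against NF on each substrate, each pair of substrates within NF and within CAF, and the differences of the treatment effect between substrates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Expression is given in CPM (counts-per-million of the TMM-scaled library size) as mean ± SD. For a group with 0 counts, a fold is given as a bound against 3 counts over the group. Tests are 2-sided.

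The tests, the contrasts, the gene lists and the alternatives were fixed before the data were examined, apart from the additions stated here. The 26 gene lists held 460 genes, of which 440 were tested. They were those of the TGF-beta/SMAD response, BMP response, contractile genes, fibroblast markers, collagen chains, matrix glycoproteins, collagen processing, matrix degradation, integrins, YAP/TAZ targets, inflammation, interferon response, proliferation, p53, hypoxia, glycolysis, cholesterol synthesis, unfolded protein response, NRF2, immediate early genes, heat shock, lung fibroblast identity, mitochondrial transcripts, and epithelial, endothelial and immune cell markers. The 20 untested genes were CD3E, CD68, CDH5, EMCN, ERG, FGF10, ITGAM, KCNMB1, KRT14, KRT5, LYZ, MEOX2, MMP13, MMP9, OGN, PTPRC, RSAD2, SFTPC and TYROBP, which had too few counts, and SOD2, whose symbol was not matched. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 26 lists of a contrast.

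Genes were named by a rule. It took the 5 genes per direction with the largest fold change among called genes with at least 5 CPM in the higher group and no overlap between the groups. For the differences of treatment effects the condition on overlap was dropped. Non-coding genes and clone names were left out. It also took up to 3 called members of each list per contrast, and ACTA2, TAGLN, CNN1, COL1A1, COL3A1, FN1, POSTN, FAP, CCN2, ANKRD1, MMP1, LOX, IL6 and MKI67 in each treatment contrast whatever their result. A few genes that the rule took are not reported here. Part of the list members so taken are given only as counts.

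The alternatives fixed beforehand were DESeq2 size factors within edgeR, no filter on low counts, DESeq2 1.42.0 on the same genes, a model of only the groups compared, the replicate letter as a term, each library left out in turn, an estimated correlation between genes in camera, limma's fry in place of camera, and correlations over genes with a mean of at least 10 CPM. Other analyses were added after seeing the data. These were a filter of at least 1 CPM, removal of each library's trend along transcript length and GC content (loess with a span of 0.3, available for 99.8% of the genes tested), omission of the libraries of letter A, omission of the stiff libraries, and contrasts of the mean of both treatment labels.

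The test was tried on simulated counts drawn from the fitted means and library sizes for the treatment effect in 2D, with 20054 genes. Of genes changed 1.5-fold it recovered 6 of 67, of those changed 2-fold 33 of 67 and of those changed 4-fold 62 of 66. It called 107 genes, 6 of them wrongly, and 0 in the unchanged soft groups. A length trend added to the simulation raised the wrong calls to 322 of 442, and removal of the trend brought them to 9 of 109. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.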

Results

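RNA was sequenced from MRC5 cells, an established human lung fibroblast line, to set fibroblasts on collagen scaffolds of 2 crosslinking levels beside fibroblasts on a flat culture surface. The control cells were named normal fibroblasts (NF) by the labels, and the same line treated with TGFB1, the cytokine that turns fibroblasts into contractile, matrix-producing cells, was named cancer-associated fibroblasts (CAF). Each kind was grown in 2D, on a soft collagen I scaffold (0.01% of the crosslinker BDDGE) and on a stiff one (1% BDDGE). Scaffold cultures lasted 7 days and cells were detached with trypsin, per the labels. There were 6 groups of 3 libraries, 18 in all, with replicates lettered A, B and C. Gene counts per library ranged from 62190684 (NF 2D replicate C) to 84073624 (NF soft replicate C). For replicates A, B and C they were 71248511, 74220210 and 62190684 in NF 2D and 75671420, 79538525 and 68049561 in CAF 2D. On the soft scaffold they were 79060255, 75635737 and 84073624 in NF and 68869198, 75530595 and 75401333 in CAF. On the stiff scaffold they were 70627261, 70586182 and 79815567 in NF and 67729887, 63521860 and 65963418 in CAF. Whether replicates were separate cultures was not stated, so the p-values below measure only the spread between these libraries, which may be technical.

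Of 58825 genes, 20054 had enough counts to be tested, and genes with at least 1 count numbered between 17182 (NF 2D replicate C) and 22580 (CAF stiff replicate A) per library. NF 2D replicate C stood apart. Its most frequent low count was 30, against 4 to 14 in the other 17 libraries, and ribosomal protein genes took 7.198% of its counts. Across the 18 libraries the most frequent low count fell as the number of detected genes, from the same counts, rose (Pearson r = -0.85, Spearman rho = -0.956). The 2-sided permutation p was 1e-05 for each and after adjustment over 1 relation, the least 1e+05 resamples give. Without NF 2D replicate C and CAF soft replicate B, the libraries farthest from the median, r was -0.924 and rho -0.937 (permutation p = 1e-05, n = 16). Within the tables of 6 libraries r was -0.892 for 2D, -0.964 for the soft and -0.914 for the stiff scaffold. The 10 most abundant genes held 7.4% to 8.7% of counts in the NF libraries in 2D and on the soft scaffold and 13.5% to 15.2% in the CAF libraries there. On the stiff scaffold the order was the other way round, with 16.9% to 18.9% in libraries labelled NF and 7.8% to 8.5% in libraries labelled CAF.

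**Figure D1:**
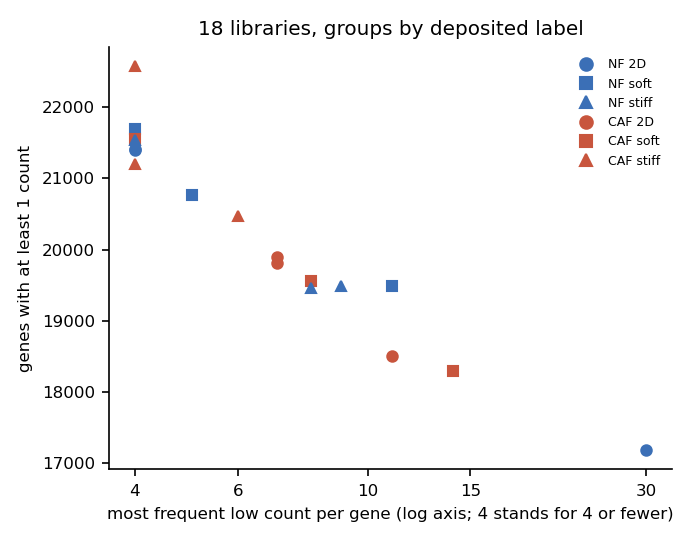
Number of genes with at least 1 count (vertical axis) against the most frequent low count (horizontal axis) for each of the 18 libraries, coloured by group. NF 2D replicate C lies apart at a low count of 30 and 17182 genes.

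The first question was what TGFB1 treatment did to fibroblasts in 2D. Several contractile and matrix genes rose in treated cells. ACTA2, the smooth muscle actin of myofibroblast stress fibres, rose from 73.6 ± 2.94 to 323 ± 16.2 CPM (log2FC 2.14 ± 0.17, adjusted p = 9e-08) (mean ± SD, n = 3 libraries per group here and below; log2FC is the log2 fold change ± SE). FN1, which encodes the matrix glycoprotein fibronectin, rose from 10420 ± 4384 to 47380 ± 4669 CPM (log2FC 2.18 ± 0.23, adjusted p = 2.3e-06). POSTN, encoding the matricellular protein periostin, rose from 16.8 ± 7.33 to 608 ± 50.2 CPM (log2FC 5.18 ± 0.36, adjusted p = 1.5e-08). Of the TGF-beta/SMAD response list, 14 of 18 rose and 0 fell (14 and 0 adjusted over the list alone, higher count first here and below, camera adjusted p = 1.3e-44). NOX4, which encodes a hydrogen peroxide-producing oxidase, rose from 2.14 ± 0.277 to 30.4 ± 2.74 CPM (log2FC 3.83 ± 0.2, adjusted p = 4.1e-10). SMAD7, a feedback inhibitor, rose too (log2FC 2.2 ± 0.14, adjusted p = 6e-09). Of the contractile list 10 of 19 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.1e-11). The transcriptional coactivator MYOCD rose (log2FC 2.32 ± 0.24, adjusted p = 1.5e-06). Tropomyosin TPM1 (log2FC 2.04 ± 0.13, adjusted p = 5.8e-09) and calponin CNN1 (log2FC 1.32 ± 0.2, adjusted p = 0.00013) rose as well.

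Matrix genes moved in both directions in 2D. Of 21 tested collagen chains 10 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 1.8e-09, adjusted p = 0.12 with an estimated correlation). COL1A1, a chain of type I collagen, rose from 11650 ± 1584 to 26880 ± 2577 CPM (log2FC 1.21 ± 0.14, adjusted p = 8.5e-06). The change of COL3A1 did not pass (log2FC 0.55 ± 0.18, adjusted p = 0.063). It passed without NF 2D replicate A (0.64, adjusted p = 0.04). Matrix glycoproteins and proteoglycans had 13 of 27 higher and 6 lower (16 and 7 adjusted over the list alone, camera adjusted p = 2.8e-07, adjusted p = 0.12 with an estimated correlation). The cartilage matrix gene COMP rose from 0.098 ± 0.0852 to 2.82 ± 0.457 CPM (log2FC 4.77 ± 0.76, adjusted p = 0.00026). Collagen processing and crosslinking genes had 11 of 18 higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 6.3e-06, adjusted p = 0.12 with an estimated correlation). The lysyl oxidase LOX (log2FC 1.32 ± 0.21, adjusted p = 0.00026) and the lysyl hydroxylase PLOD2 (log2FC 1.09 ± 0.22, adjusted p = 0.0026) rose. Among matrix degradation genes 5 of 22 rose and 3 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.13 with an estimated correlation). ADAM12, a membrane metalloprotease, rose (log2FC 3.74 ± 0.28, adjusted p = 3.9e-08). So did the collagenase MMP1 (log2FC 1.52 ± 0.17, adjusted p = 5.7e-06). ADAMTS1 fell (log2FC -2.4 ± 0.22, adjusted p = 3.7e-07).

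Markers of cancer-associated fibroblasts had 4 of 12 higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 4.1e-05). The surface protease FAP rose from 50.4 ± 20.8 to 213 ± 12.2 CPM (log2FC 2.08 ± 0.22, adjusted p = 3.3e-06). YAP/TAZ targets had 6 of 22 higher and none lower (8 and 1 adjusted over the list alone, camera adjusted p = 6.6e-05, adjusted p = 0.13 with an estimated correlation). ANKRD1 rose from 5.68 ± 0.44 to 65.9 ± 6.94 CPM (log2FC 3.54 ± 0.34, adjusted p = 7e-07). IGFBP3 (log2FC 4.52 ± 0.29, adjusted p = 5.5e-09) and CCN2 (log2FC 1.32 ± 0.12, adjusted p = 5.9e-07) rose too. Integrins and focal adhesion genes had 5 of 23 higher and 5 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.42 with an estimated correlation). Their median log2FC was 0.22 and their mean -0.12. The collagen-binding chain ITGA11 rose (log2FC 2.48 ± 0.19, adjusted p = 5.6e-08). The chain ITGB8 fell (log2FC -2.73 ± 0.42, adjusted p = 0.00017). Unfolded protein and amino acid response genes had 10 of 16 higher and none lower (11 and 0 adjusted over the list alone, camera adjusted p = 5.9e-08). The chaperone HYOU1 was 1 of them (log2FC 1.1 ± 0.17, adjusted p = 0.00018). With an estimated correlation the calls of the TGF-beta/SMAD, contractile, fibroblast marker and unfolded protein lists held in 2D (adjusted p = 8.6e-06, 0.014, 0.0075 and 0.039).

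Some members of the inflammatory, interferon and lung fibroblast identity lists were lower in treated cells. VCAM1, an adhesion molecule for leukocytes, fell from 6.95 ± 2.49 to 0.225 ± 0.24 CPM (log2FC -4.98 ± 0.65, adjusted p = 5.3e-05). The chemokine CCL2 fell (log2FC -1.65 ± 0.18, adjusted p = 4.6e-06). Interferon response genes had 3 of 19 lower and none higher (1 and 6 adjusted over the list alone, camera adjusted p = 0.004, adjusted p = 0.051 with an estimated correlation). Lung fibroblast identity genes had 5 of 10 lower and 1 higher (1 and 5 adjusted over the list alone, camera adjusted p = 6.6e-05, adjusted p = 0.051 with an estimated correlation). The growth factor HGF fell (log2FC -1.93 ± 0.3, adjusted p = 0.00024). Of 7 epithelial markers 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.16 with an estimated correlation). It was the keratin KRT19 (log2FC -2.71 ± 0.35, adjusted p = 2.4e-05). Proliferation genes had 2 of 31 higher (1 and 0 adjusted over the list alone, camera adjusted p = 8e-04, adjusted p = 0.33 with an estimated correlation). MKI67 did not pass (log2FC 0.36 ± 0.22, adjusted p = 0.37). IL6 did not pass either (log2FC 0.5 ± 0.26, adjusted p = 0.29). The smooth muscle gene TAGLN passed (log2FC 0.69 ± 0.2, adjusted p = 0.034), a call that was lost without NF 2D replicate A (0.56), NF 2D replicate B (0.65), CAF 2D replicate B (0.65) or CAF 2D replicate C (0.63).

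The other lists had no camera call in 2D. BMP and inhibitor-of-differentiation genes had 2 of 15 higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.4). Inflammatory cytokines and NF-kB targets had 1 of 23 higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.14). The p53 targets had 1 of 18 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.62). Hypoxia genes had 2 of 18 higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.44). Glycolysis genes had 1 of 18 higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.88). Cholesterol synthesis genes had 0 of 22 higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.4). NRF2 targets had 0 of 15 higher and 4 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.082). Immediate early genes had 4 of 18 higher and 4 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.4). Heat shock genes had 0 of 12 higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.88). Mitochondrially encoded transcripts had 0 of 13 higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.34). Markers of other cell types were measured too. Endothelial markers had 1 of 6 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.67). Immune cell markers had 0 of 4 higher and 0 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.59). Single members still passed. EGR2, an early growth response transcription factor, rose from 0.0942 ± 0.105 to 9.51 ± 1.38 CPM (log2FC 6.58 ± 0.61, adjusted p = 4.5e-07). BHLHE40, a hypoxia-inducible repressor, rose (log2FC 2.34 ± 0.14, adjusted p = 1.8e-09). BMP4 fell (log2FC -2.84 ± 0.27, adjusted p = 7.8e-07). ID3, an inhibitor of differentiation, rose (log2FC 1.75 ± 0.31, adjusted p = 0.00072). The median and mean log2FC differed in sign for the BMP list (0.05 and -0.19).

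In all, 1855 of 20054 genes differed in 2D, 795 higher and 1060 lower in treated cells (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). By at least 2-fold, 380 rose and 633 fell. ACTC1, the cardiac actin, rose (log2FC 6.87 ± 0.63, adjusted p = 3.8e-07), as did EGR2 and POSTN. The adaptor gene PIK3AP1 (log2FC 4.9 ± 0.61, adjusted p = 2.1e-05) and the adhesion gene AMIGO2 (log2FC 4.78 ± 0.2, adjusted p = 3e-11) completed the 5 largest rises. The 5 largest falls were those of VCAM1, the periplakin gene PPL (log2FC -5 ± 0.34, adjusted p = 1e-08), SLC7A14 (log2FC -4.82 ± 0.63, adjusted p = 3.3e-05), the globin HBD (log2FC -4.23 ± 0.75, adjusted p = 0.00079) and the receptor ADGRG1 (log2FC -4.11 ± 0.33, adjusted p = 6.8e-08). These were the largest among genes of at least 5 CPM in the higher group with no overlap of the groups. ACTC1 and HBD have near-identical relatives, and reads could have been shared between them. Without NF 2D replicate A, 2886 genes passed. A fit of the 2D groups alone called 772. With each library's trend along transcript length and GC content removed, which was chosen after seeing the data, 1500 were higher and 1365 lower, so the larger direction was not stable.

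Genes named for the treatment effect in 2D have these places in the RefSeq annotation of GRCh38.p14. ACTA2 (ENSG00000107796.13) is on chromosome 10, 88935074 to 88991337, and FN1 (ENSG00000115414.19) on chromosome 2, 215360865 to 215436068. POSTN (ENSG00000133110.15) is on chromosome 13, 37562585 to 37598768, and COL1A1 (ENSG00000108821.13) on chromosome 17, 50184101 to 50201631. MKI67 (ENSG00000148773.14) is on chromosome 10, 128096659 to 128126423. Counts covered whole genes, so no exon or UTR is singled out.

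**Figure D2:**
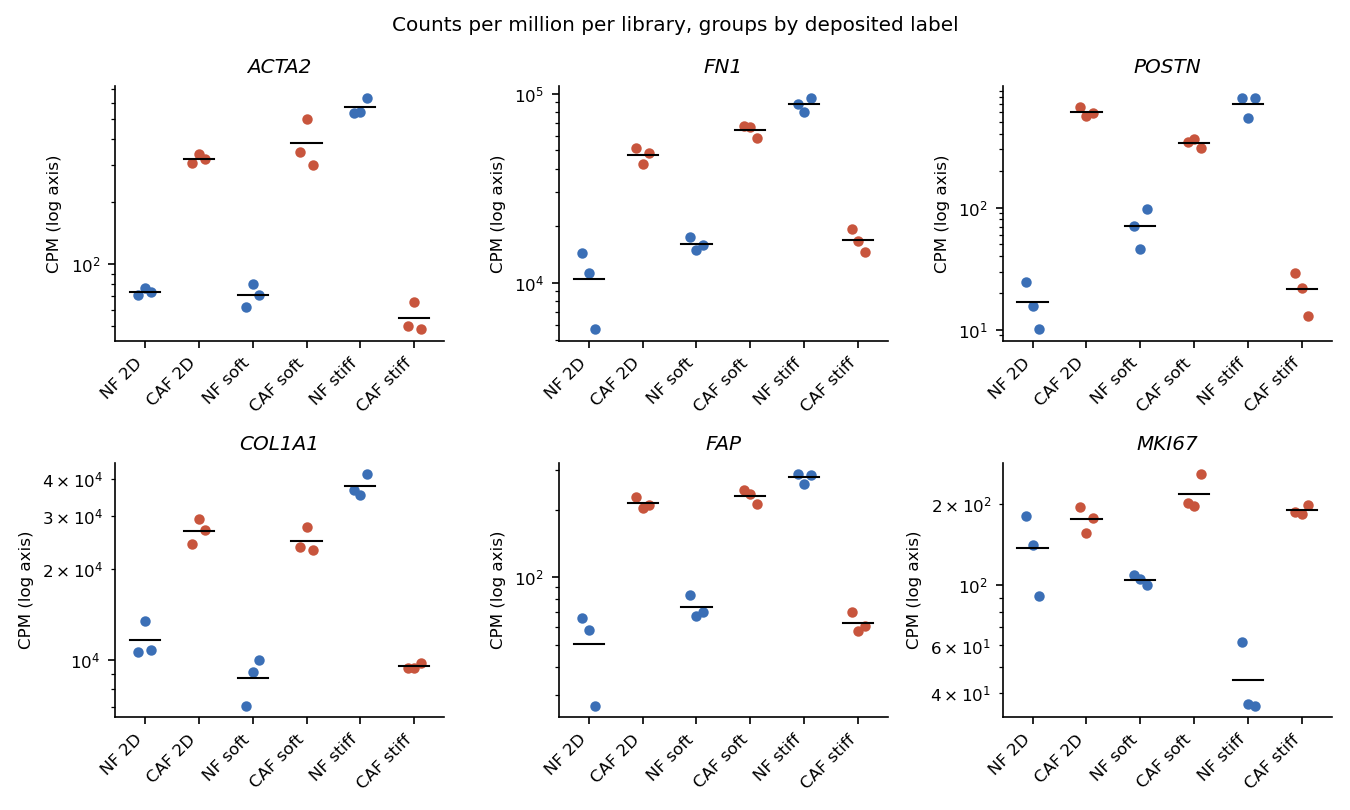
Expression in CPM (vertical log axis) of ACTA2, FN1, POSTN, COL1A1, FAP and MKI67 in each of the 18 libraries, by group as labelled, with a line at each group's mean. ACTA2, FN1, POSTN, COL1A1 and FAP were higher in CAF in 2D and on the soft scaffold and lower in the libraries labelled CAF on the stiff scaffold.

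On the soft scaffold the question was the same. Most contractile and matrix genes named for 2D rose here too. ACTA2 rose from 70.9 ± 9.1 to 384 ± 106 CPM (log2FC 2.44 ± 0.18, adjusted p = 2e-08). FN1 rose from 16080 ± 1307 to 64050 ± 5127 CPM (log2FC 1.99 ± 0.23, adjusted p = 5.4e-06). POSTN rose from 71.4 ± 25.9 to 338 ± 27.9 CPM (log2FC 2.24 ± 0.32, adjusted p = 6.1e-05). COL1A1 (log2FC 1.51 ± 0.14, adjusted p = 4.8e-07) and FAP (log2FC 1.65 ± 0.22, adjusted p = 3.4e-05) rose. CNN1 (log2FC 1.18 ± 0.2, adjusted p = 0.00034) and ANKRD1 (log2FC 2.69 ± 0.33, adjusted p = 1.3e-05) rose. MMP1 rose from 88.4 ± 16.4 to 547 ± 81.8 CPM (log2FC 2.63 ± 0.18, adjusted p = 9.9e-09). CCN2 did not pass (log2FC 0.3 ± 0.12, adjusted p = 0.15). TAGLN passed (log2FC 0.67 ± 0.2, adjusted p = 0.037) but not without NF soft replicate A (0.58) or C (0.67) or CAF soft replicate B (0.48) or C (0.74). LOX passed (log2FC 0.67 ± 0.21, adjusted p = 0.048) but not without NF soft replicate B (0.57) or C (0.55) or CAF soft replicate A (0.65), B (0.6) or C (0.75). IL6 was lower (log2FC -0.98 ± 0.26, adjusted p = 0.019), a call lost without NF soft replicate A (-0.72) or CAF soft replicate A (-1.01) or C (-0.84). COL3A1 did not pass (log2FC 0.49 ± 0.18, adjusted p = 0.1) except without NF soft replicate C (0.66).

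Of the TGF-beta/SMAD list 13 of 18 rose and 0 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.2e-30). NOX4 rose from 2.87 ± 0.65 to 40.8 ± 8.88 CPM (log2FC 3.83 ± 0.2, adjusted p = 4.9e-10). Contractile genes had 9 of 19 higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 1.5e-13). Fibroblast markers had 4 of 12 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0018). Collagen chains had 9 of 21 higher and 5 lower (12 and 5 adjusted over the list alone, camera adjusted p = 2.2e-08, adjusted p = 0.17 with an estimated correlation). COL10A1, a collagen of hypertrophic cartilage, rose from 0.173 ± 0.172 to 10.6 ± 3.5 CPM (log2FC 5.91 ± 0.66, adjusted p = 4.5e-06). Matrix glycoproteins had 14 of 27 higher and 8 lower (15 and 9 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.3 with an estimated correlation). Collagen processing genes had 7 of 18 higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.35 with an estimated correlation). Matrix degradation genes had 6 of 22 higher and 3 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.18 with an estimated correlation).

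Cell cycle genes rose with treatment on the soft scaffold. Of 31 proliferation genes 19 rose and none fell (23 and 0 adjusted over the list alone, camera adjusted p = 1.3e-14). MKI67, the proliferation antigen Ki-67, rose from 105 ± 4.43 to 218 ± 34.1 CPM (log2FC 1.06 ± 0.22, adjusted p = 0.0028). So did cyclin A2 CCNA2 (log2FC 1.38 ± 0.19, adjusted p = 3.5e-05), the transcription factor FOXM1 (log2FC 1.3 ± 0.17, adjusted p = 3.7e-05) and the mitotic kinase PLK1 (log2FC 1.16 ± 0.19, adjusted p = 0.00038). Inflammatory genes had 9 of 23 lower and none higher (0 and 11 adjusted over the list alone, camera adjusted p = 1.5e-09). VCAM1 had 0 counts in the 3 treated libraries and was at least 1920-fold lower than in controls (26.9 ± 11.4 CPM, floor of 3 counts over the group). The bound was 1270 or 1250 without CAF soft replicate B or C. The chemokine CXCL8 fell from 4.94 ± 0.951 to 0.682 ± 0.307 CPM (log2FC -2.86 ± 0.43, adjusted p = 0.00013). Interferon genes had 6 of 19 lower (0 and 9 adjusted over the list alone, camera adjusted p = 0.00029). Lung fibroblast identity genes had 5 of 10 lower and 1 higher (1 and 8 adjusted over the list alone, camera adjusted p = 3.3e-07). HGF fell from 101 ± 29.8 to 12.3 ± 2.54 CPM (log2FC -3.03 ± 0.32, adjusted p = 1.9e-06). With an estimated correlation these 4 calls held (adjusted p = 0.038, 0.00052, 0.016 and 0.016). So did those of the TGF-beta/SMAD (5.4e-05), contractile (0.0094) and fibroblast marker lists (0.016).

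Metabolic and stress lists had calls on the soft scaffold that were lost with an estimated correlation. The p53 targets had 1 of 18 higher and 5 lower (1 and 8 adjusted over the list alone, camera adjusted p = 0.00058, adjusted p = 0.081 with an estimated correlation). PLK2 (log2FC -2.11 ± 0.19, adjusted p = 2.2e-07) and BTG2 (log2FC -1.14 ± 0.17, adjusted p = 0.00015) fell. Glycolysis genes had 1 of 18 higher and 7 lower (1 and 9 adjusted over the list alone, camera adjusted p = 0.0028, adjusted p = 0.35 with an estimated correlation). Cholesterol synthesis genes had 0 of 22 higher and 3 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.39 with an estimated correlation). Unfolded protein response genes had 3 of 16 higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.35 with an estimated correlation). NRF2 targets had 1 of 15 higher and 4 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.29 with an estimated correlation). The ferritin light chain FTL fell (log2FC -1.36 ± 0.27, adjusted p = 0.0023). BMPER, a BMP modulator, fell (log2FC -2.79 ± 0.24, adjusted p = 1.4e-07). In all 2037 genes differed, 906 higher and 1131 lower, of which 435 and 627 by at least 2-fold. With the length and GC trend removed it was 1790 higher and 1472 lower. ADH1B, an alcohol dehydrogenase with near-identical relatives, was at least 935-fold lower in treated cells (620 or 609 without CAF soft replicate B or C, 603 without NF soft replicate C). The flavin monooxygenase FMO2 was at least 591-fold lower (392 or 385 without CAF soft replicate B or C). Both had 0 counts there, and their bounds have the same limit as that of VCAM1.

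Whether the treatment effect differed between soft scaffold and 2D was tested directly. The effects were alike across genes. Pearson r of the log2 fold changes was 0.354 and Spearman rho 0.456 over 20054 genes. They were 0.858 and 0.778 over the 9108 genes with a mean of at least 10 CPM (genes are not independent replicates). Of 1221 genes called on both substrates 1217 had the same direction, 531 higher and 686 lower, where independent lists would share 35.9 and 59.8. The test of the difference itself called 31 genes, 3 with a more positive effect on the soft scaffold and 28 with a more negative one. That balance was unstable, with 59 and 71 by DESeq2, 52 and 78 with no filter on low counts and 39 and 54 with the length and GC trend removed. POSTN rose less there (difference -2.93 ± 0.44, adjusted p = 0.0075). The synaptic pentraxin gene NPTX1 (-3.76 ± 0.52, adjusted p = 0.0039), the cytokine LIF (-1.85 ± 0.27, adjusted p = 0.0063) and the thioredoxin-binding gene TXNIP (-2.93 ± 0.29, adjusted p = 0.00014) had more negative effects. Inflammatory genes as a list had a more negative effect (0 higher and 2 lower of 23, 0 and 6 adjusted over the list alone, camera adjusted p = 6e-12, adjusted p = 3e-04 with an estimated correlation). For MKI67 the difference did not pass (0.70 ± 0.31, adjusted p = 0.843). The count was unstable too. It was 10 without NF 2D replicate B, 20, 9 and 9 without CAF 2D replicate A, B or C, 19 and 8 without NF soft replicate A or C, and 10, 14 and 20 without CAF soft replicate A, B or C.

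On the stiff scaffold the treatment effect, as labelled, had the opposite sign for most genes that responded elsewhere. Directions below are those between libraries labelled CAF and libraries labelled NF. ACTA2 was lower in the libraries labelled CAF, from 573 ± 55.1 to 54.7 ± 9.33 CPM (log2FC -3.39 ± 0.18, adjusted p = 3e-10). FN1 was lower, from 87800 ± 7767 to 16820 ± 2419 CPM (log2FC -2.38 ± 0.23, adjusted p = 4.4e-07). POSTN was lower, from 707 ± 146 to 21.4 ± 8.13 CPM (log2FC -5.05 ± 0.36, adjusted p = 1e-08). COL1A1 was lower, from 37770 ± 3221 to 9533 ± 183 CPM (log2FC -1.99 ± 0.14, adjusted p = 1.2e-08). FAP (log2FC -2.15 ± 0.22, adjusted p = 1.1e-06) and CCN2 (log2FC -1.18 ± 0.12, adjusted p = 1.4e-06) were lower. So were ANKRD1 (log2FC -2.49 ± 0.33, adjusted p = 1.8e-05) and LOX (log2FC -1.58 ± 0.21, adjusted p = 2.3e-05). COL3A1 (-2.17 ± 0.19), TAGLN (-1.13 ± 0.2), CNN1 (-1.61 ± 0.2) and IL6 (-1.32 ± 0.26) were lower as well, with adjusted p = 1.1e-07, 0.00049, 8.6e-06 and 0.0014. MMP1 did not pass (log2FC -0.43 ± 0.17, adjusted p = 0.11). MKI67 was higher in the libraries labelled CAF, from 44.7 ± 14.7 to 189 ± 8.1 CPM (log2FC 2.08 ± 0.22, adjusted p = 1.8e-06). In 2D and on the soft scaffold the share of counts in the 10 most abundant genes was also higher in CAF, and here it was lower.

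Of the TGF-beta/SMAD list 16 of 18 were lower and 1 higher in libraries labelled CAF (1 and 16 adjusted over the list alone, camera adjusted p = 8.6e-51). NOX4 went from 73.3 ± 10.8 to 2.46 ± 0.0921 CPM (log2FC -4.9 ± 0.21, adjusted p = 2.3e-11). TGFBI, a TGF-beta-induced matrix protein, was lower (log2FC -3.27 ± 0.16, adjusted p = 1.4e-10). Contractile genes had 13 of 19 lower (0 and 14 adjusted over the list alone, camera adjusted p = 8.1e-22). Collagen chains had 15 of 21 lower (1 and 16 adjusted over the list alone, camera adjusted p = 1.1e-29). Matrix glycoproteins had 5 of 27 higher and 16 lower (5 and 16 adjusted over the list alone, camera adjusted p = 6.1e-14). Collagen processing genes had 1 of 18 higher and 12 lower (1 and 13 adjusted over the list alone, camera adjusted p = 2.4e-10). Matrix degradation genes had 4 of 22 higher and 10 lower (4 and 12 adjusted over the list alone, camera adjusted p = 0.00019). Fibroblast markers had 3 of 12 higher and 6 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.00027). Unfolded protein response genes had 9 of 16 lower (0 and 10 adjusted over the list alone, camera adjusted p = 7.6e-09). ELN, encoding elastin, was lower (log2FC -6.94 ± 0.38, adjusted p = 3.8e-10). So were COMP (log2FC -5.24 ± 0.72, adjusted p = 3e-05) and the collagen COL4A1 (log2FC -2.95 ± 0.24, adjusted p = 4.9e-08).

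Proliferation genes were higher in libraries labelled CAF on the stiff scaffold, 29 of 31 with none lower (31 and 0 adjusted over the list alone, camera adjusted p = 2.7e-46). The kinesin KIF20A went from 11.1 ± 5.92 to 84.9 ± 10.5 CPM (log2FC 2.93 ± 0.27, adjusted p = 3e-07). Cyclin B1 CCNB1 (log2FC 2.64 ± 0.2, adjusted p = 2.1e-08) and CDC20 (log2FC 2.54 ± 0.26, adjusted p = 1e-06) were higher. With an estimated correlation the calls of the proliferation (0.00097), TGF-beta/SMAD (3.9e-06), contractile (0.00097), collagen (0.0084), matrix glycoprotein (0.018), collagen processing (0.023), matrix degradation (0.018), fibroblast marker (0.0084) and unfolded protein lists (0.018) held, each as an adjusted p. Heat shock genes had 7 of 12 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.00062, adjusted p = 0.12 with an estimated correlation). HGF was higher, from 8.38 ± 2.31 to 92.5 ± 29 CPM (log2FC 3.47 ± 0.32, adjusted p = 2.9e-07). VCAM1 was higher, from 0.744 ± 0.5 to 4.5 ± 1.02 CPM (log2FC 2.6 ± 0.57, adjusted p = 0.004). Large differences included those of the pentraxins NPTX1 (log2FC 7.65 ± 0.48, adjusted p = 2.4e-09), and PTX3 (log2FC 5.31 ± 0.21, adjusted p = 6.6e-12) and the growth factor GDF5 (log2FC 4.95 ± 0.56, adjusted p = 3.2e-06), which were higher in libraries labelled CAF. EGR2 (log2FC -8.81 ± 0.64, adjusted p = 1.3e-08), ACTC1 (log2FC -7.12 ± 0.65, adjusted p = 2.4e-07) and the potassium channel KCNH1 (log2FC -6.52 ± 0.96, adjusted p = 7.3e-05) were lower.

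In all 2919 genes differed between the labels on the stiff scaffold, 1632 higher and 1287 lower in libraries labelled CAF. By at least 2-fold, 794 were higher and 697 lower. Against the 2D effect, Pearson r of the log2 fold changes was -0.326 and Spearman rho -0.305 over 20054 genes. They were -0.654 and -0.436 over the 9108 genes with at least 10 CPM. Of 1182 genes called in both, 1128 had opposite signs. Against the soft scaffold r was -0.312 and rho -0.272 (-0.599 and -0.375 over the 9108 genes), and 1131 of 1282 genes called in both had opposite signs. The remaining 151 had the same sign, 128 of them higher, where independent lists would share 73.7 higher genes. Genes are not independent replicates, so these correlations carry no p-value.

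**Figure D3:**
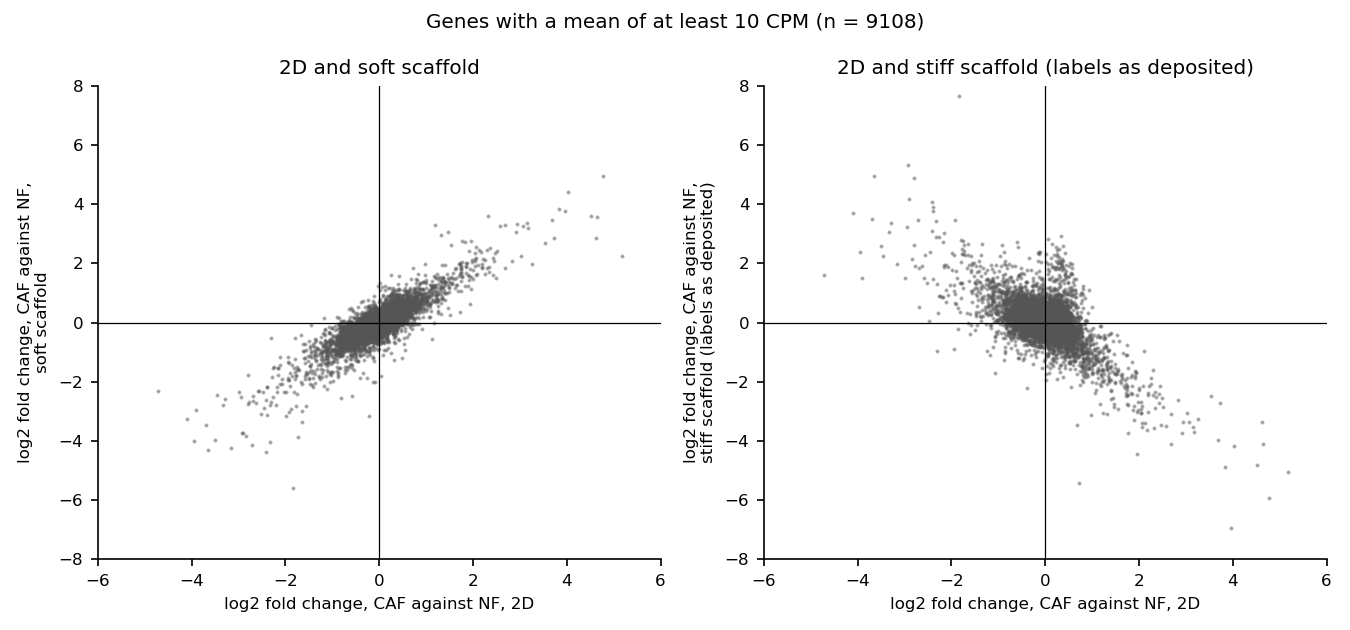
Log2 fold change of CAF over NF on the soft and on the stiff scaffold (vertical axes) against that in 2D (horizontal axes) for 9108 genes with a mean of at least 10 CPM, 2 of them outside the axes. Pearson r was 0.858 for the soft scaffold and -0.654 for the stiff scaffold as labelled.

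The difference of the treatment effect between stiff scaffold and 2D passed for 3525 genes, 1977 with a more positive and 1548 with a more negative effect as labelled on the stiff scaffold. The difference between the scaffolds passed for 3416, 1927 more positive and 1489 more negative (2291 and 2350 with the length and GC trend removed). For ACTA2 the difference from 2D was -5.53 ± 0.25 (adjusted p = 1.1e-11) and that from the soft scaffold -5.83 ± 0.25 (adjusted p = 5.9e-12). POSTN differed by -10.22 ± 0.51 and -7.29 ± 0.48 (adjusted p = 3.7e-11 and 1.3e-09). NOX4 differed by -8.73 ± 0.29 and -8.73 ± 0.29 (adjusted p = 2.6e-13 and 3.1e-13). HGF had a more positive effect by 5.39 ± 0.44 and 6.49 ± 0.45 (adjusted p = 3.1e-08 and 3.3e-09). The TGF-beta/SMAD list had 15 of 18 more negative against 2D (1 and 15 adjusted over the list alone, camera adjusted p = 1.1e-59). Against soft it had 15 of 18 (1 and 15 adjusted over the list alone, camera adjusted p = 1.5e-52). Both calls held with an estimated correlation (adjusted p = 2.7e-06 and 4.2e-06). Proliferation genes had 23 of 31 more positive against 2D (24 and 0 adjusted over the list alone, camera adjusted p = 3.2e-12, adjusted p = 0.043 with an estimated correlation). Against soft they had 19 of 31 (21 and 0 adjusted over the list alone, camera adjusted p = 4.4e-06, adjusted p = 0.17 with an estimated correlation).

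**Figure D4:**
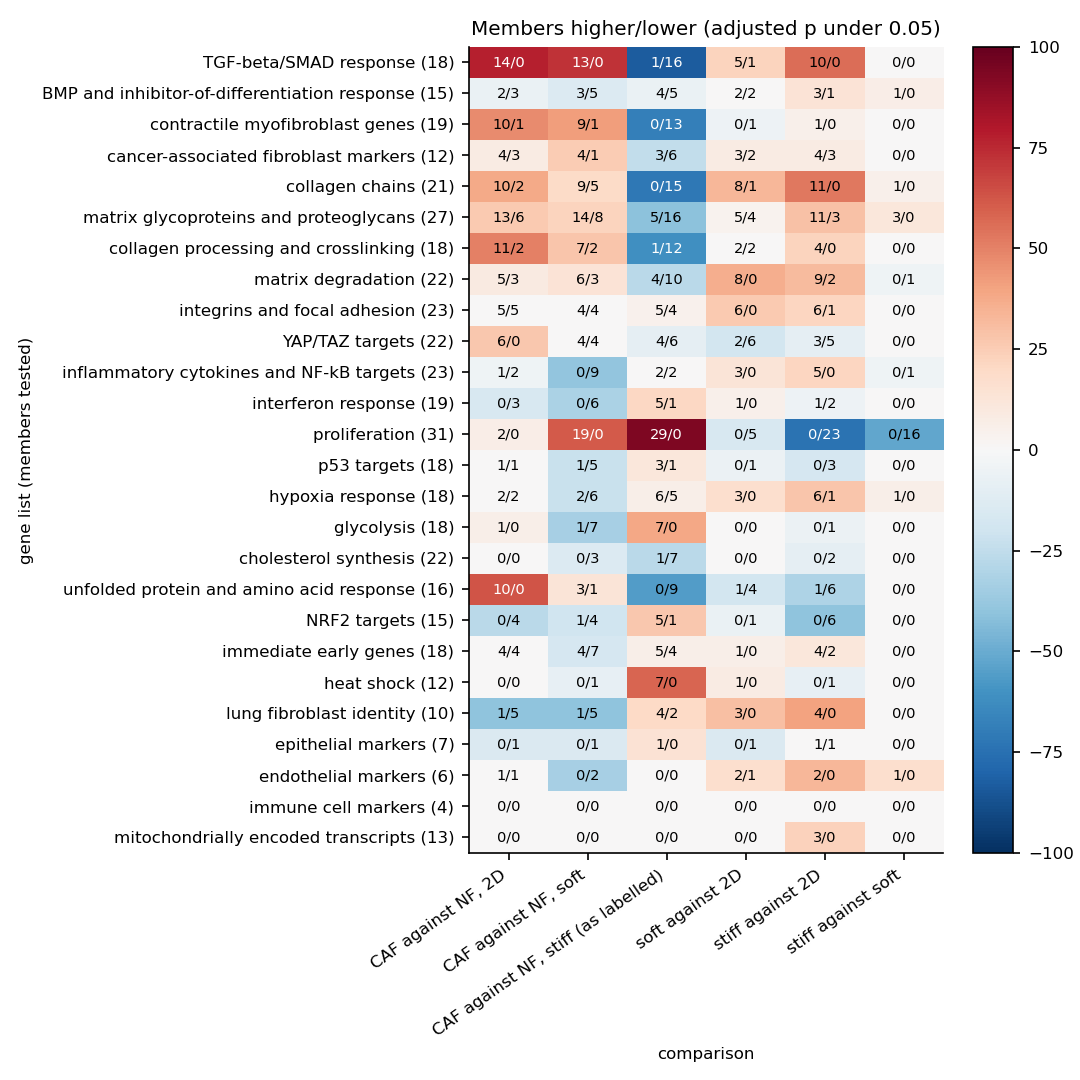
Number of tested members higher and lower for each of the 26 gene lists (vertical axis) in 6 comparisons (horizontal axis), coloured by higher minus lower members as percent of those tested. The TGF-beta/SMAD list had 14 of 18 higher in 2D, 13 on the soft scaffold and 1 higher with 16 lower between the labels on the stiff scaffold.

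The next question was what the scaffold itself did to gene expression. On the soft scaffold against 2D, CXCL12, the stromal chemokine SDF-1 (GRCh38.p14 chromosome 10, 44370165 to 44385097), was lower in both kinds of cells. In NF it fell from 30.6 ± 1.21 to 4.95 ± 0.518 CPM (log2FC -2.62 ± 0.17, adjusted p = 9.4e-08) and in CAF from 36.3 ± 2.22 to 2.43 ± 0.269 CPM (log2FC -3.9 ± 0.18, adjusted p = 2.9e-10). The protease inhibitor A2M rose from 12.8 ± 1.98 to 187 ± 31.9 CPM (log2FC 3.87 ± 0.31, adjusted p = 1.8e-06) in NF. In CAF it rose from 2.59 ± 1.19 to 52.5 ± 13.6 CPM (log2FC 4.34 ± 0.33, adjusted p = 5.1e-07). In NF the alcohol dehydrogenase ADH1B (log2FC 4.86 ± 0.77, adjusted p = 0.0029), the metalloprotease ADAMTS8 (log2FC 4.48 ± 0.59, adjusted p = 0.00023) and the complement gene C3 (log2FC 3.87 ± 0.41, adjusted p = 2.7e-05) rose as well. In CAF the acid phosphatase ACP3 (log2FC 5.7 ± 0.59, adjusted p = 1.6e-05), INMT (log2FC 3.05 ± 0.32, adjusted p = 1.9e-05) and the stromelysin MMP3 (log2FC 2.95 ± 0.45, adjusted p = 0.00089) rose. The receptor ROR1 (log2FC -2.29 ± 0.42, adjusted p = 0.0049) and ANKRD1 (log2FC -2.22 ± 0.32, adjusted p = 0.00049) fell. BMP4 rose in CAF (log2FC 1.68 ± 0.27, adjusted p = 0.0013).

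In NF 409 genes differed (289 higher on the soft scaffold, 120 lower) and in CAF 368 (239 higher, 129 lower). Fits of the groups compared alone called 36 in NF (34 higher, 2 lower) and 571 in CAF. With the length and GC trend removed NF had 481 higher and 409 lower and CAF 448 and 426. Each substrate was deposited as its own table, so a batch that follows the tables cannot be told apart from the substrate. The NF and CAF calls shared 109 higher and 33 lower genes, where independent lists would share 3.4 and 0.8, and 3 genes went opposite ways. Inflammatory genes rose in NF, 4 of 23 (8 and 0 adjusted over the list alone, camera adjusted p = 1e-10, adjusted p = 0.00086 with an estimated correlation). CXCL8 rose from 0.941 ± 0.223 to 4.94 ± 0.951 CPM (log2FC 2.39 ± 0.42, adjusted p = 0.0031). Matrix degradation genes rose in NF (5 of 22, 10 and 1 adjusted over the list alone, camera adjusted p = 1.6e-09, adjusted p = 0.0023 with an estimated correlation). They also rose in CAF (6 of 22, 10 and 1 adjusted over the list alone, camera adjusted p = 3.7e-08, adjusted p = 0.0065 with an estimated correlation). Proliferation genes fell in NF, 5 of 31 (0 and 13 adjusted over the list alone, camera adjusted p = 4.8e-14, adjusted p = 0.048 with an estimated correlation). Unfolded protein response genes fell in CAF, 4 of 16 (1 and 10 adjusted over the list alone, camera adjusted p = 9.3e-09, adjusted p = 0.042 with an estimated correlation). TGF-beta/SMAD genes were higher in NF (3 of 18, 8 and 1 adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.033 with an estimated correlation). So were lung fibroblast identity genes (3 of 10, 6 and 0 adjusted over the list alone, camera adjusted p = 5.1e-06, adjusted p = 0.033 with an estimated correlation). YAP/TAZ targets were lower in CAF, 4 of 22 with 1 higher (1 and 7 adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.2 with an estimated correlation). The NF count was 271 without NF 2D replicate B and 206 without NF soft replicate C. The CAF count was 209, 225 and 210 without CAF 2D replicate A, B or C and 224 or 235 without CAF soft replicate A or B.

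The mean of both kinds of cells, a comparison chosen after seeing the data, called 949 genes, 583 higher on the soft scaffold and 366 lower (187 and 76 by at least 2-fold). With the length and GC trend removed 873 were higher and 1023 lower. Large rises were those of the chitinase-like protein CHI3L1 (log2FC 4.64 ± 0.35, adjusted p = 1.9e-07), A2M (log2FC 4.11 ± 0.23, adjusted p = 4e-09), ACP3 (log2FC 3.85 ± 0.37, adjusted p = 2.7e-06) and BMP2 (log2FC 2.51 ± 0.28, adjusted p = 1.4e-05). CXCL12 (log2FC -3.26 ± 0.12, adjusted p = 8.5e-12), the membrane repair protein dysferlin DYSF (log2FC -1.91 ± 0.16, adjusted p = 5.2e-07) and ODC1, the first enzyme of polyamine synthesis (log2FC -1.47 ± 0.14, adjusted p = 1.5e-06), fell. Matrix degradation genes had 8 of 22 higher and none lower (11 and 1 adjusted over the list alone, camera adjusted p = 1.3e-11, adjusted p = 0.0014 with an estimated correlation). Collagen chains had 8 of 21 higher and 1 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.00064, adjusted p = 0.38 with an estimated correlation). Epithelial markers had 1 of 7 lower, KRT19 (log2FC -1.46 ± 0.24, adjusted p = 8e-04; 0 and 2 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.28 with an estimated correlation). Endothelial markers had 2 of 6 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.15). PECAM1 (log2FC 4.82 ± 0.87, adjusted p = 0.0028, 0.054 without letter A) and VWF (log2FC 1.48 ± 0.41, adjusted p = 0.042) were higher and TIE1 (log2FC -1.92 ± 0.26, adjusted p = 0.00013) lower. The call of VWF was lost without NF 2D A (0.066) or B (0.09), CAF 2D A (0.11) or B (0.09), NF soft A (0.087) or C (0.11), CAF soft A (0.079) or B (0.081). Mitochondrially encoded transcripts had 0 of 13 higher (5 and 0 adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.38 with an estimated correlation). Their share of counts was 3.202% to 4.417% in the 4 scaffold libraries of letter A and 0.69% to 2.122% in the others.

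**Figure D5:**
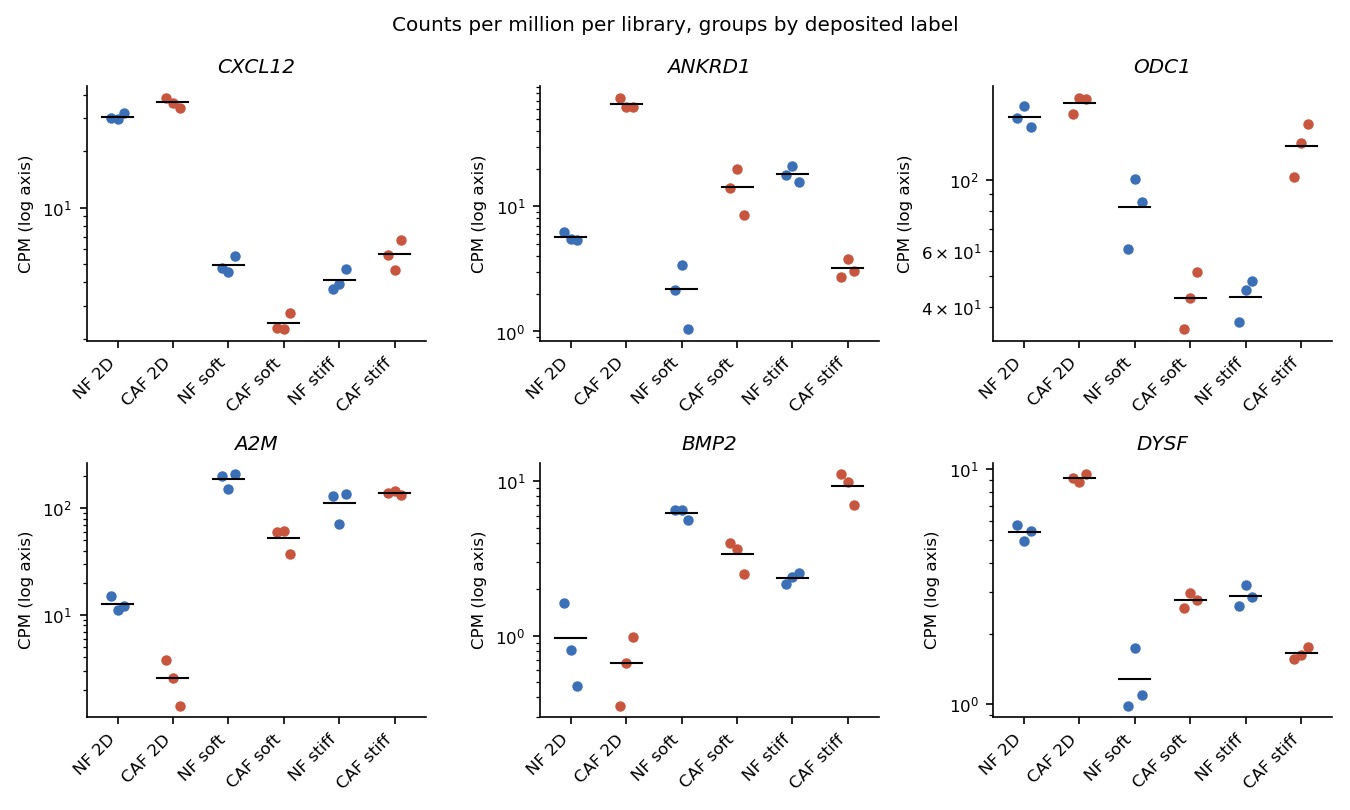
Expression in CPM (vertical log axis) of CXCL12, ANKRD1, ODC1, A2M, BMP2 and DYSF in each of the 18 libraries, by group as labelled, with a line at each group's mean. CXCL12 was lower and A2M higher on the soft scaffold than in 2D in both NF and CAF.

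Within labels, stiff scaffold against 2D would hold treatment if stiff labels were exchanged. Between libraries labelled NF, contractile genes had 12 of 19 higher and none lower on the stiff scaffold (13 and 0 adjusted over the list alone, camera adjusted p = 7.6e-16, adjusted p = 0.0038 with an estimated correlation). ACTA2 went from 73.6 ± 2.94 to 573 ± 55.1 CPM (log2FC 2.96 ± 0.18, adjusted p = 1.1e-09). POSTN went from 16.8 ± 7.33 to 707 ± 146 CPM (log2FC 5.4 ± 0.37, adjusted p = 5e-09). NOX4 (log2FC 5.1 ± 0.21, adjusted p = 9.9e-12), COMP (log2FC 7.07 ± 0.81, adjusted p = 3.3e-06) and the metalloproteases MMP11 (log2FC 5.53 ± 0.38, adjusted p = 5.9e-09) and MMP10 (log2FC 7.25 ± 1.81, adjusted p = 0.0083) were higher too. TGF-beta/SMAD genes had 15 of 18 higher (16 and 1 adjusted over the list alone, camera adjusted p = 3.4e-52, adjusted p = 5.5e-06 with an estimated correlation). Collagen chains had 16 of 21 higher (18 and 0 adjusted over the list alone, camera adjusted p = 8.3e-30, adjusted p = 0.0062 with an estimated correlation). Proliferation genes had 27 of 31 lower (0 and 28 adjusted over the list alone, camera adjusted p = 3.5e-35, adjusted p = 0.0024 with an estimated correlation). KIF20A went from 95 ± 14.9 to 11.1 ± 5.92 CPM (log2FC -3.09 ± 0.28, adjusted p = 1.5e-07). SLC7A14 (log2FC -5.82 ± 0.68, adjusted p = 4.3e-06), the lipid phosphatase-related PLPPR4 (log2FC -5.87 ± 0.55, adjusted p = 2.7e-07) and GDF5 (log2FC -5.43 ± 0.57, adjusted p = 1.2e-06) were lower. In all 3301 genes differed (1509 higher, 1792 lower), or 1555 (826, 729) in a fit of these groups alone.

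Between libraries labelled CAF the TGF-beta/SMAD list went the other way. ACTA2 was lower on the stiff scaffold, from 323 ± 16.2 to 54.7 ± 9.33 CPM (log2FC -2.56 ± 0.18, adjusted p = 9.7e-09). POSTN went from 608 ± 50.2 to 21.4 ± 8.13 CPM (log2FC -4.83 ± 0.36, adjusted p = 2.3e-08). TGF-beta/SMAD genes had 13 of 18 lower and 1 higher (1 and 16 adjusted over the list alone, camera adjusted p = 1.2e-32, adjusted p = 3.3e-05 with an estimated correlation). Contractile genes had 9 of 19 lower and 1 higher (1 and 12 adjusted over the list alone, camera adjusted p = 8.2e-15, adjusted p = 0.0038 with an estimated correlation). Unfolded protein response genes had 11 of 16 lower (0 and 14 adjusted over the list alone, camera adjusted p = 3.7e-15, adjusted p = 0.0038 with an estimated correlation). Lung fibroblast identity genes had 5 of 10 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.017 with an estimated correlation). HGF went from 7.85 ± 1.44 to 92.5 ± 29 CPM (log2FC 3.56 ± 0.32, adjusted p = 2.7e-07). CHI3L1 (log2FC 8.44 ± 0.59, adjusted p = 1.1e-08), ACP3 (log2FC 7.26 ± 0.61, adjusted p = 1.1e-07), ADAMTS8 (log2FC 7 ± 0.74, adjusted p = 1.8e-06) and the collectin COLEC10 (log2FC 6.32 ± 0.8, adjusted p = 1.7e-05) were higher. Proliferation genes had 0 of 31 higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.092). In all 2126 genes differed, 1209 higher and 917 lower (1424 and 1723 with the length and GC trend removed).

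The mean over both labels, which does not depend on which stiff libraries bear which label and was chosen after seeing the data, called 1722 genes, 898 higher and 824 lower on the stiff scaffold (1088 and 1523 with the length and GC trend removed). CHI3L1 (log2FC 5.27 ± 0.36, adjusted p = 3e-08), A2M (log2FC 4.44 ± 0.23, adjusted p = 1.3e-09) and ACP3 (log2FC 3.96 ± 0.37, adjusted p = 1.8e-06) were higher. CXCL12 (log2FC -2.79 ± 0.12, adjusted p = 9.3e-11) and DYSF (log2FC -1.69 ± 0.16, adjusted p = 1.7e-06) were lower. Proliferation genes had 23 of 31 lower and none higher (0 and 27 adjusted over the list alone, camera adjusted p = 2.1e-43, adjusted p = 0.0023 with an estimated correlation). Matrix degradation genes had 9 of 22 higher and 2 lower (10 and 3 adjusted over the list alone, camera adjusted p = 2.4e-09, adjusted p = 0.0023 with an estimated correlation). Inflammatory genes had 5 of 23 higher (6 and 0 adjusted over the list alone, camera adjusted p = 0.00053, adjusted p = 0.032 with an estimated correlation). TGF-beta/SMAD genes had 10 of 18 higher and none lower (12 and 1 adjusted over the list alone, camera adjusted p = 4.3e-08, adjusted p = 0.01 with an estimated correlation). Lung fibroblast identity genes had 4 of 10 higher (7 and 0 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.032 with an estimated correlation). Mitochondrially encoded transcripts had 3 of 13 higher (6 and 0 adjusted over the list alone, camera adjusted p = 0.00022, adjusted p = 0.38 with an estimated correlation).

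The last question was stiffness, which exchanged stiff labels would mix with treatment. Libraries labelled NF differed in 2414 genes (1039 higher, 1375 lower on the stiff scaffold). Those labelled CAF differed in 1666 (908 and 758, or 1185 and 1394 with the trend removed). In libraries labelled NF ACTA2 went from 70.9 ± 9.1 to 573 ± 55.1 CPM (log2FC 3.02 ± 0.18, adjusted p = 1.2e-09). In libraries labelled CAF it went from 384 ± 106 to 54.7 ± 9.33 CPM (log2FC -2.81 ± 0.18, adjusted p = 5.1e-09). TGF-beta/SMAD genes had 14 of 18 higher and 1 lower in NF (16 and 1 adjusted over the list alone, camera adjusted p = 8.6e-49, adjusted p = 4.5e-06 with an estimated correlation). In CAF 15 were lower and none higher (0 and 15 adjusted over the list alone, camera adjusted p = 3.7e-43, adjusted p = 9e-06 with an estimated correlation). PRG4, the lubricin gene, had 0 counts in NF on the soft scaffold and was at least 447-fold higher in libraries labelled NF on the stiff one (5.41 ± 3.48 CPM), or 295-fold and 293-fold without NF soft replicate A or C. COL10A1 was higher in NF (log2FC 7.55 ± 0.7, adjusted p = 3e-07). NPTX1 (log2FC -7.35 ± 0.48, adjusted p = 4e-09) and PSG1 (log2FC -6.08 ± 0.56, adjusted p = 3e-07), 1 of a family of near-identical genes, were lower. In libraries labelled CAF SLC7A14 (log2FC 6.23 ± 0.71, adjusted p = 7.3e-06), NPTX1 (log2FC 5.91 ± 0.43, adjusted p = 2.9e-08) and the interleukin receptor IL6R (log2FC 4.75 ± 0.87, adjusted p = 0.0011) were higher and AMIGO2 (log2FC -5.24 ± 0.2, adjusted p = 1.3e-11) lower. Proliferation genes had 24 of 31 lower in NF (0 and 24 adjusted over the list alone, camera adjusted p = 4.1e-21, adjusted p = 0.016 with an estimated correlation). Inflammatory genes had 5 of 23 higher in CAF (10 and 0 adjusted over the list alone, camera adjusted p = 5.3e-05, adjusted p = 0.0086 with an estimated correlation).

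The mean over both labels, again chosen after seeing the data, called 103 genes between the scaffolds, 25 higher and 78 lower on the stiff one, against 1489 at an unadjusted p under 0.05. As a mean, 16 of 31 proliferation genes were lower on the stiff scaffold and none higher (0 and 23 adjusted over the list alone, camera adjusted p = 8.7e-55, adjusted p = 0.0013 with an estimated correlation). Between libraries labelled CAF alone 1 was lower and 0 higher (0 and 0 adjusted over the list alone, median log2FC -0.12, camera adjusted p = 0.17), against 24 lower for NF. Among them KIF20A was lower (log2FC -1.04 ± 0.18, adjusted p = 0.013), a call that was lost without CAF soft replicate C (-0.94), NF stiff replicate C (-0.99) or CAF stiff replicate B (-1). GPCPD1 was higher (log2FC 0.73 ± 0.11, adjusted p = 0.0065) and TMEM171 lower (log2FC -1.05 ± 0.17, adjusted p = 0.0097). BMP and inhibitor-of-differentiation genes had 1 of 15 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.025 with an estimated correlation). TGF-beta/SMAD genes had none (4 and 0 adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.036 with an estimated correlation). Collagen chains had 1 of 21 higher (8 and 0 adjusted over the list alone, camera adjusted p = 7e-09, adjusted p = 0.17 with an estimated correlation). The count of 103 was 51, 44 and 57 without NF soft replicate A, B or C, 68 and 28 without CAF soft replicate B or C, 43 and 28 without NF stiff replicate B or C, and 39, 29 and 59 without CAF stiff replicate A, B or C.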

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

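The explanations weighed here and the counts of other splits were tested after the results were seen, and the contrasts of the mean of both labels were also chosen then. What called for a closer look was in each case the test of the difference in treatment effect between substrates. The test for a library far from its group was not applied, since groups had 3 libraries.

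Between the soft scaffold and 2D the treatment effect differed for 31 genes. It was more positive on the soft scaffold for ACP3 (log2 difference 3.7), SULF1 (1.63) and MLPH (1.37). It was more negative for NPTX1 (-3.76), C3 (-3.13), POSTN (-2.93), TXNIP (-2.93) and CCN2 (-1.02). VCAM1, with 0 counts in treated cells on the soft scaffold, differed with an adjusted p = 0.042. Several of these calls were lost when 1 library was left out, with the adjusted p then reached in parentheses. That of ACP3 was lost without NF 2D A (0.052) and B (0.13), CAF 2D B (0.15) and C (0.083), NF soft A (0.08), B (0.11) and C (0.17), CAF soft A (0.12), B (0.13) and C (0.081). For SULF1 these were NF 2D A (0.065) and B (0.093), CAF 2D A (0.07), B (0.14) and C (0.14), NF soft A (0.069), B (0.084) and C (0.16), CAF soft A (0.12) and B (0.14). For MLPH they were NF 2D B (0.078), CAF 2D A (0.068), B (0.08) and C (0.087), NF soft A (0.069) and C (0.11), CAF soft A (0.067), B (0.061) and C (0.081). The call of C3 ended without NF 2D B (0.11), CAF 2D B (0.12) and C (0.13), NF soft A (0.062) and C (0.12), CAF soft A (0.094) and B (0.093). The call of CCN2 ended without NF 2D B (0.083), CAF 2D B (0.08) and C (0.072), NF soft C (0.096), CAF soft A (0.069) and C (0.056). VCAM1 lost its call without NF 2D B (0.11) and C (0.061), CAF 2D C (0.2), NF soft A (0.069) and C (0.11), CAF soft A (0.12), B (0.14) and C (0.13).

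Between the stiff scaffold as labelled and 2D the effect differed for 3525 genes. It was more positive for SLC7A14 (log2 difference 10.09), NPTX1 (9.5), PSG1 (9.11), GDF5 (8.61), PRKG2 (8.55) and MKI67 (1.72). Most negative were COL10A1 (-15.72), EGR2 (-15.39), ACTC1 (-13.99), TYRP1 (-11.57) and KCNH1 (-11.09). Groups near 0 counts make such sizes uncertain here and below (COL10A1 had 7 in NF 2D). Other genes were ACTA2 (-5.53), TAGLN (-1.82), CNN1 (-2.93), COL1A1 (-3.19), COL3A1 (-2.72), FN1 (-4.57), POSTN (-10.22), LOX (-2.9) and MMP1 (-1.95). Further genes were FAP (-4.24), CCN2 (-2.5), ANKRD1 (-6.03) and IL6 (-1.82).

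Between the stiff scaffold as labelled and the soft one the effect differed for 3416 genes. It was more positive for NPTX1 (log2 difference 13.26), SLC7A14 (11.97) and MKI67 (1.03). Genes with 0 counts in a group are given without a fold. Among them ADH1B (adjusted p = 1.7e-06), VCAM1 (6.2e-08) and FMO2 (1.9e-05) had more positive effects and PRG4 (3.3e-06) a more negative one. Most negative were COL10A1 (-16.55), ACTC1 (-13.64), EGR2 (-13.24) and TYRP1 (-12.67). Other genes were ACTA2 (-5.83), TAGLN (-1.8), CNN1 (-2.79), COL1A1 (-3.5), COL3A1 (-2.66), FN1 (-4.38), POSTN (-7.29), LOX (-2.24) and MMP1 (-3.06). Further genes were FAP (-3.8), CCN2 (-1.48) and ANKRD1 (-5.19).

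Pattern 1 was the opposite sign of the treatment response between the labels on the stiff scaffold, and the tables argue against a length and GC trend as its cause, since with the trend removed 1669 of the 1816 genes called in 2D and on the stiff scaffold still had opposite signs. Labels exchanged in the stiff table and a stiff substrate that turns the response round, the biological alternative, both stay open. A score over the 1217 genes that followed treatment in 2D and on the soft scaffold put 6 of the 6 stiff libraries on the other label's side of its midpoint (1.01), but this restates the opposite signs and is what either explanation gives. An exchange with the same response on every substrate is argued against for proliferation genes, whose median log2FC was 1.8 between the stiff labels and also positive in 2D (0.3) and on the soft scaffold (0.8). Libraries labelled CAF on stiff differed in 15 genes from NF and in 1666 from CAF on soft. Those labelled NF differed in 1114 from CAF and in 2414 from NF there. Each was nearer the other label, which fits an exchange but is not decisive. Directions within a stiff label may be the other label's.

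Pattern 2 was NF 2D replicate C, with 17182 genes detected and a most frequent low count of 30, and no biological explanation was tested for it. Genomic DNA stays open, as protein-coding genes had the lowest share of counts (96.988%, next 97.203%). The fewest genes of 1 to 20 counts (1698) go against it. More PCR copies per molecule stay open. Low count and genes detected come from the same counts, so any loss of low counts could give their negative r. It was -0.924 without the 2 farthest libraries, this one among them. Against NF 2D replicates A and B its ratio also followed transcript length (Spearman rho -0.635) and GC content (0.488) over 10471 genes, so loss of long transcripts was not separated from copying.

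Pattern 3 was the set of 949 genes that differed between the soft scaffold and 2D as a mean of both labels. A length and GC trend is argued against as its cause, as 902 of them were also called with the trend removed, and so is NF 2D replicate C, as 903 were also called without it. A batch that follows the 3 tables cannot be told apart from the substrate, since each substrate is a table of its own. The mean over labels called 103 genes between the soft and stiff tables, which leaves both open. An effect of the collagen scaffold itself is the biological alternative that stays untested.

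Other splits of the libraries were compared with the real ones. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. The highest other split called 0 genes for the treatment effect in 2D (real value 1855), on the soft scaffold (2037) and on the stiff scaffold (2919), where 1 split, the real one, reached the real value. It also called 0 for stiff scaffold against 2D in NF (3301) and CAF (2126) and for stiff against soft scaffold in NF (2414) and CAF (1666). For soft scaffold against 2D it called 1 gene in CAF (368). In NF it called 764 against the real 409, in a split of 2D replicate C with soft replicates B and C against the others, and 2 splits reached the real value. For the differences of treatment effects and the means, 33 splits were compared. Chance was excluded for the difference of stiff scaffold and 2D (3525 genes, highest other 1141), for stiff against soft scaffold (3416, highest other 1199) and for the mean of soft scaffold against 2D (949, highest other 59). Chance was not excluded for the difference of soft scaffold and 2D, where 3 splits reached 31 genes and the highest, which exchanged NF and CAF of 2D replicates A and B, called 738. That points to sample structure, as exchanged treatments within 1 table turn the treatment effect into a difference. The mean of stiff against soft scaffold called 103 genes. The highest other split, which exchanged CAF soft and stiff replicates B and C, called 812. Sample structure shows there too. For the mean of stiff scaffold against 2D (1722) the highest other split, all CAF libraries exchanged, called 3525. It is the difference in treatment effect.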

How the results depend on the processing

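The filter of at least 1 CPM, removal of the length and GC trend, omission of letter A and omission of the stiff libraries were chosen after seeing the data. No named gene, list or correlation reversed under any alternative, but the larger direction of several counts did. With the trend removed it turned for the treatment effect in 2D (1500 higher, 1365 lower) and on the soft scaffold (1790, 1472), stiff scaffold against 2D in CAF (1424, 1723) and as a mean (1088, 1523), stiff against soft in CAF (1185, 1394), the mean of soft scaffold against 2D (873, 1023) and the difference of stiff against soft (2291, 2350). In a model of only the groups compared it turned for stiff scaffold against 2D in NF (826, 729). The cause of these changes was not tested, apart from the smaller number of libraries where some were left out. Under DESeq2, 919 of 922 gene results kept their direction and side of the threshold, called or not, 1 lost its call and 2 gained one. With DESeq2 size factors in edgeR 914 kept both and 8 lost the call, and with no filter 903 did and 18 lost it. A model of only the groups compared kept 812 and lost 102. At 1 CPM or more 874 were kept and 1 lost, and with the trend removed 914 and 4. Without letter A 796 were kept and 126 lost, and without the stiff libraries 274 and 50. With single libraries left out, 6531 results kept both and 853 lost the call. Of 390 list results, called or not, 269 kept both with an estimated correlation and 121 lost a call. Under fry 307 kept both, 39 lost a call and 44 gained one. Size factors moved the share of higher calls by under 10 points and the median of all genes by under 0.1. What depth limits was not tested apart from the number of libraries. At the depth of these libraries 9% of simulated 1.5-fold changes, in genes of at least 1 CPM, were recovered for the treatment effect in 2D.

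Counts of called genes moved by over 1.5 times in these cases. With no filter, soft scaffold against 2D in NF called 696 (409 as reported), the difference of treatment effects between soft scaffold and 2D 130 (31) and the mean of stiff against soft scaffold 269 (103). DESeq2 called 833 and 861 for soft scaffold against 2D in NF and CAF (368), 130 for the soft difference, 305 for the mean of stiff against soft and 1627 for the mean of soft scaffold against 2D (949). With the trend removed the treatment effect called 2865 in 2D (1855) and 3262 on the soft scaffold (2037). Soft scaffold against 2D then called 890 in NF and 874 in CAF, stiff against soft in CAF 2579 (1666) and the soft difference 93. The means called 291 for stiff against soft, 1896 for soft against 2D and 2611 for stiff against 2D (1722). Without letter A, soft scaffold against 2D called 270 in NF and 186 in CAF, the soft difference 9 and the mean of soft against 2D 587. Without the stiff libraries these were 270, 207, 11 and 612. In a model of only the groups compared they were 36, 571, 11 and 615, and the treatment effect in 2D called 772 and stiff scaffold against 2D in NF 1555 (3301).

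With each library left out in turn the treatment effect in 2D ranged from 1309 to 2886 genes, the highest without NF 2D replicate A. Soft scaffold against 2D ranged from 206 (without NF soft replicate C) to 478 in NF, where it was 271 without NF 2D replicate B. In CAF it ranged from 209 to 255, with 209, 225 and 210 without CAF 2D replicate A, B or C and 224 or 235 without CAF soft replicate A or B. The soft difference ranged from 8 to 41. It was 10 without NF 2D replicate B, 20, 9 and 9 without CAF 2D A, B or C, 19 and 8 without NF soft A or C, and 10, 14 and 20 without CAF soft A, B or C. The mean of stiff against soft ranged from 28 to 141. It was 51, 44 and 57 without NF soft A, B or C, 68 and 28 without CAF soft B or C, 43 and 28 without NF stiff B or C, and 39, 29 and 59 without CAF stiff A, B or C. Correlations of the treatment effects ranged from 0.284 to 0.347 (2D and soft), -0.331 to -0.272 (2D and stiff) and -0.312 to -0.257 (soft and stiff). Over genes of at least 10 CPM they were 0.858, -0.654 and -0.599. Without NF 2D replicate C the means of soft and stiff scaffold against 2D called 1364 and 2468, within 1.5 times of the reported counts.

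The replicate letter as a block was tried as well. Deviations from group means correlated by 0.074 to 0.27 between A libraries (15 pairs). For B and C it was -0.045 to 0.077 and -0.009 to 0.141 (15 pairs each). Libraries of letter A thus deviated together. Of 18 libraries 10 correlated best with 1 of their own letter (6 A and 4 C), a hint from the data, not the design. With the block the treatment effect in 2D called 2929, soft scaffold against 2D 828 in NF and 759 in CAF, stiff scaffold against 2D in CAF 3194, stiff against soft in CAF 2538 and the soft difference 80 (26 more positive, 54 more negative). The means called 273 for stiff against soft, 1778 for soft against 2D and 2768 for stiff against 2D. The larger direction of the last turned (1383, 1385). Of gene results 917 kept both, 3 lost the call and 2 gained it. With the letter within each substrate as block the soft difference called 67. These numbers of gene results were then 387, 11 and 1.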

Other observations

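Means of both labels were chosen after seeing the data. Hypoxia response genes were higher on the stiff scaffold than in 2D as a mean of both labels, 6 of 18 with 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.00022, adjusted p = 0.14 with an estimated correlation). On the soft scaffold against 2D 3 of 18 were higher and none lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.38 with an estimated correlation). Between libraries labelled CAF, 5 of 19 interferon genes were higher on stiff than soft and none lower. Adjusted over the list alone it was 8 and 0 (camera adjusted p = 0.0013, adjusted p = 0.033 with an estimated correlation). Exchanged stiff labels would mix this with treatment.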
